A study of Homo sapiens with 5 samples.

How the data were processed

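RNA from 5 TE7 clones was measured on Affymetrix Gene 2.0 ST arrays, 1 array per clone, with 2 control clones and 3 CDH26 clones. Per the labels' protocols, cells were transduced with a control or a CDH26 construct, clones were grown from single cells to confluence and held for 24 h at 1.8 mM calcium, and total RNA was labelled with biotin. Affymetrix Expression Console was used per the submitters' processing notes; its version, the summarisation method, the background correction and the genome build are not given in the sources used here. Clones were assigned to groups from the labels.

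The values analysed were the authors' deposited table of log values, taken here as log2. In every row the values of the 2 control clones were equal and opposite, with a largest absolute sum of 1e-06, so the authors centred each probe set on the control mean; no level is kept. The direction is a CDH26 or control clone relative to that mean. The deposited values ran from −3.02 to 7.35 and had a median of 0 on each array. Base 10 was excluded by the size of the largest values; natural logarithms were not, and were tried as an alternative. Exact ties between arrays were common: 46.3% of genes had a different value on each array (values within 1e-05 counted as tied), and 377 genes had the same value on all arrays, for reasons not recorded.

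The annotation of the array named 15835 probe sets, each with 1 gene, 0 with several, and left 28772 unnamed; all 15835 names matched the current symbol of their gene identifier in the RefSeq annotation of GRCh38.p14. That annotation was used only for names, gene lengths and the order of neighbouring genes, and no coordinates are given because the build behind the table is not stated.

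Before the data were examined, a filter on dim genes, the choice of the brightest probe set per gene and a repeat of quantile normalization had been fixed. None of these can be applied to centred values, which hold no brightness. All 14812 named genes were therefore tested, and the mean was taken over the probe sets of the 651 genes with more than 1; both had been listed beforehand as alternatives. A repeated quantile normalization would force control and CDH26 arrays to the same spread and was not run, nor was a stricter brightness filter.

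Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The estimated prior degrees of freedom were 0.885. An exact permutation of 2 against 3 clones cannot give a p below 0.1, so none was used for single genes. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, adjusted over the 24 lists tested of 25 fixed. The integrin list had too few named members. Estimated correlations and fry were run as alternatives; fry's directional test asks whether a list's genes move one way on balance, its mixed test whether they differ in either direction, and neither compares the list with other genes.

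Genes were named by a rule fixed beforehand: CDH26, then up to 12 genes in each direction past the adjusted threshold, filled, where too few passed, by size from genes with at least a 2-fold difference, an unadjusted p under 0.05 and no overlap between the clones of the groups, and the 2 members of each list with the smallest unadjusted p. Only 5 genes qualified in the negative direction.

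On simulated data with each gene's own spread over 14812 genes, the limma step called 73 of 100 genes changed by 1 log2 unit and 96 of 100 changed by 3, and 14 of 14612 unchanged genes. The 2-fold criterion called 53, 100 and 8 of the same genes. The changed genes were drawn at random from all genes with any spread, and planting many changes eases the adjusted threshold. These shares are therefore not the power of the real comparison, where CDH26, at 2.84 ± 0.13 (SE), had an adjusted p of 0.25 in limma. The list test, run on simulated values of the same genes with 1 of 24 lists shifted by 0.5, called that list and 0 others; genes were simulated as independent.

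Alternatives were centring on array medians, trend and robust variance, array weights, a replicate block, each clone left out in turn, an adjusted threshold of 0.1 and the other list tests. Chosen after seeing the data were single named probe sets, all probe sets, genes without ties, natural logarithms and the estimated correlation under other alternatives. Figures were drawn with matplotlib 3.10.9.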

Results

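Gene expression was measured in 5 single-cell-derived clones of TE7, a human esophageal carcinoma cell line. Of these, 2 clones carried a control construct and 3 carried a construct expressing CDH26, which encodes a cadherin, a member of the family of calcium-dependent adhesion proteins. All clones were held for 24 h at 1.8 mM calcium before RNA was taken, and each was hybridised to 1 Affymetrix Gene 2.0 ST array. The deposited table held 44607 probe sets, of which 15835 carried the name of 1 gene and together covered 14812 genes. The values are logarithms relative to the mean of the 2 control clones, so they give differences between clones and no expression level. They are given below as log2, the most common base for such arrays; the base itself is not recorded. The number of arrays limits the precision of every value.

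The clones differed from one another within groups as well as between them. Between control clones 1 and 2, 183 genes differed by at least 1 log2 unit, against 9 genes between CDH26 clones 1 and 2. CDH26 clone 3 differed by that much from CDH26 clone 1 in 75 genes and from CDH26 clone 2 in 62, from control clone 1 in 33 and from control clone 2 in 157. Control clone 2 lay at least 0.5 log2 units beyond all other arrays in 468 genes, and control clone 1 did so in 116. Clones of 1 construct are separate clones, so the spread within a group includes differences between clones as well as array error.

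The first comparison asked whether the construct raised the CDH26 transcript. CDH26 was higher by 2.84 ± 0.13 log2 units (SE; 95% interval 2.48 to 3.20), a 7.16-fold difference, in the clones that carried it. The values were 2.87, 3.01 and 2.63 in CDH26 clones 1, 2 and 3, a mean of 2.84 ± 0.19 (SD, n = 3), and 0.01 and −0.01 in the control clones. With limma and Benjamini-Hochberg adjustment over 14812 genes the adjusted p was 0.25, so the difference did not pass the adjusted threshold of 0.05. It passed, with an adjusted p of 0.0106, when the test was restricted to the 6857 genes with a different value on each array, an alternative chosen after seeing the data.

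The second comparison asked which other transcripts differed between CDH26 and control clones. Among the genes with the largest positive differences at an unadjusted p under 0.05 without overlap between groups, several are known from stratified epithelium or from the response to interferon. CLCA2, a membrane protein of stratified epithelia, was higher by 3.74 ± 1.01 (SE) log2 units in the CDH26 clones, and KRT14, the type I keratin of basal keratinocytes, by 2.72 ± 0.43. SLFN11, a Schlafen-family protein that restricts viral protein synthesis, differed by 2.95 ± 0.51. The interferon-induced genes IFI44 and DDX60 differed by 2.50 ± 0.56 and 2.22 ± 0.48. None of these genes passed the adjusted threshold (limma, adjusted p = 0.626 for each).

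The protocadherin PCDH18 differed by 2.50 ± 0.61 (SE), the adhesion G protein-coupled receptors ADGRL2 and ADGRF1 by 2.40 ± 0.76 and 1.91 ± 0.52, and the ephrin receptor EPHA3 by 1.94 ± 0.51. EREG, which encodes the EGF receptor ligand epiregulin, differed by 2.06 ± 0.45. The transcriptional regulators EYA1 and PLAGL1 differed by 1.85 ± 0.49 and 1.81 ± 0.26. By the rule that chose them, each of the 3 CDH26 clones lay above both control clones in all 12 genes of this group. In each of them CDH26 clone 3 had the smallest departure: CLCA2 was at 4.33, 4.78 and 2.11 in clones 1, 2 and 3, and ADGRL2 at 2.85, 3.21 and 1.15. Among the 12 the control clones differed most from each other in CLCA2, at 0.56 and −0.56.

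In the other direction 5 genes had at least a 2-fold lower value together with an unadjusted p under 0.05; at any p, 75 genes were at least 2-fold higher and 21 at least 2-fold lower. With trend and robust variance 43 genes were higher and 1 lower by the criterion, and without CDH26 clone 1 or 2 15 and 16 were higher and 0 lower. KRT80, a type II keratin, had a log2 difference of −1.90 ± 0.49 (SE), and the insulin receptor substrate IRS2 one of −1.40 ± 0.33. The values were −1.36 ± 0.41 for the kinase HUNK, −1.33 ± 0.45 for the actin-binding protein nexilin (NEXN) and −1.05 ± 0.27 for FST, the activin antagonist follistatin. By the same rule all 3 CDH26 clones lay below both control clones in each of these genes. NEXN was at −0.70 without control clone 2. The adjusted p from limma was again 0.626 for each.

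**Figure D1:**
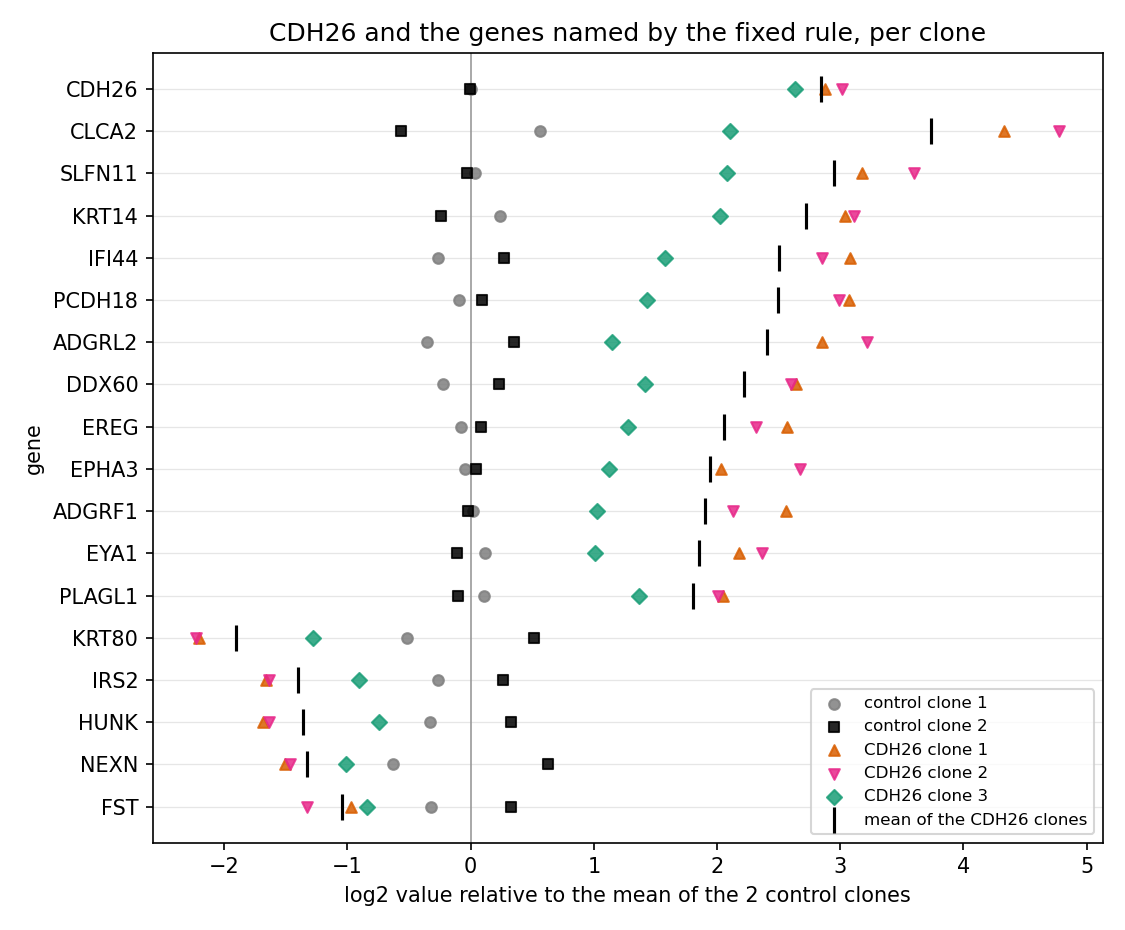
Log2 value per clone, relative to the mean of the control clones, for CDH26 and for genes with at least a 2-fold difference, an unadjusted p under 0.05 and no overlap between groups, the 12 largest positive and all 5 negative; each symbol is 1 clone and the black bar is the mean of the CDH26 clones. CDH26 lies between 2.63 and 3.01 in the CDH26 clones, while CDH26 clone 3 lies nearer to the controls than clones 1 and 2 in the other genes.

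Across all 14812 genes tested with limma, 0 passed an adjusted p of 0.05, while 520 were higher and 593 lower in CDH26 clones at an unadjusted threshold of 0.05, 1113 in all. CDH26 clones lay wholly above the control clones in 8.98% of these genes and wholly below in 9.93%, against means of 5.98% and 5.97% over the 10 ways to split the arrays into 2 and 3. Among the 6857 genes with a different value on each array the shares were 16.4% and 18.6%, against 10% each way; with either set of genes 2 of the 10 splits, the real one included, gave as large a share in total. At least a 2-fold difference together with an unadjusted p under 0.05, a description not corrected for multiple tests, was found for 48 genes, 43 higher and 5 lower, or for 112 if the deposited values are natural logarithms. Without control clone 1, 186 genes passed the adjusted threshold, 86 higher and 100 lower, and without control clone 2 again 0; in both tests the lone control clone is assumed to vary like the CDH26 clones. The number of 2-fold genes was 160 without control clone 1, where 71 were higher and 89 lower so that the balance of directions turned, 29 without control clone 2, and 15, 16 and 114 without CDH26 clones 1, 2 and 3.

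Gene lists were then compared, to ask whether genes of a pathway or cell type differed together. Of the 24 lists tested, 6 were called by camera with a preset correlation between genes, 5 towards higher and 1 towards lower values in the CDH26 clones. With a correlation estimated from the data 0 lists were called, with an adjusted p of 0.58 for each of the 6. That form of camera also uses only the few residual degrees of freedom, so few calls can survive it at any correlation. Hypoxia and glycolysis had an estimated correlation of −0.0086, below the preset 0.01, yet its unadjusted camera p rose from 0.00145 to 0.0394. For that list the loss therefore does not measure correlation between genes. The other called lists had estimates above the preset. These were 0.37 for basal squamous cell, 0.49 for interferon response and 0.48 for YAP and TAZ targets. They were 0.24 for cholesterol synthesis and 0.07 for squamous differentiation. For these lists both correlation and the few degrees of freedom enter the loss, and by these estimates the preset correlation was too low. The directional test of fry, a rotation test, called 0. Its mixed test, which asks whether members differ in either direction, called 3: cell cycle (adjusted p = 0.0224), the stress response (0.0271) and hypoxia and glycolysis (0.0375). With all clones in the fit, no member of any list passed the adjusted threshold over all genes tested.

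Markers of basal squamous cells stood furthest apart. As a list, the 14 members measured of 25 listed were higher in the CDH26 clones, with a median log2 difference of 0.42. The camera adjusted p was 1.17e-05, or 0.58 with an estimated correlation. All 14 had a higher mean in the CDH26 clones, and in 8 of them every CDH26 clone lay above both control clones. Adjusted over the list alone 2 members passed, KRT14 and SFN (adjusted p = 0.0378 for each); SFN, which encodes the cell cycle regulator 14-3-3 sigma, was higher by 0.63 ± 0.11 (SE). The list's median was 0.46, 0.57 and 0.37 in CDH26 clones 1, 2 and 3, and 0.19 and −0.19 in control clones 1 and 2. The call held with each clone left out in turn; without control clone 2 the median difference was 0.25 and the adjusted p 0.0232.

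Genes of terminal squamous differentiation, such as cornified envelope proteins and kallikreins, gave a smaller shift. The 48 members were higher as a list (camera, adjusted p = 0.0147; adjusted p = 0.58 with an estimated correlation) with a median of 0.04, and 37 had a higher mean in the CDH26 clones. Adjusted over the list alone 0 members passed. The epidermal transcription factor ZNF750 differed by 0.55 ± 0.15 (SE) and the kallikrein KLK11 by 0.66 ± 0.26. The call was lost without control clone 1 (adjusted p = 0.655) and without CDH26 clone 1 (adjusted p = 0.0537), and the median was 0.07 without control clone 2.

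The interferon response list of 33 genes was higher as a list (camera, adjusted p = 8.91e-05; adjusted p = 0.58 with an estimated correlation), with a median log2 difference of 0.36. In 27 members the mean was higher in the CDH26 clones, and in 11 every CDH26 clone lay above both control clones; adjusted over the list alone 0 passed. Beside DDX60, IFITM3, a membrane protein that blocks viral entry, differed by 0.11 ± 0.03 (SE). The list's median was 0.53, 0.41 and 0.06 in CDH26 clones 1, 2 and 3, against −0.23 and 0.23 in control clones 1 and 2, so CDH26 clone 3 lay between the controls. Without control clone 1 the call was lost (adjusted p = 0.374) and the median difference was 0.09; without control clone 2 it was 0.59, and it was 0.19 without CDH26 clone 1.

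Targets of the transcriptional coactivators YAP and TAZ were the only list called towards lower values. The 19 members had a median log2 difference of −0.31 (camera, adjusted p = 0.00174; adjusted p = 0.58 with an estimated correlation), and 16 had a lower mean in the CDH26 clones. In 8 of them every CDH26 clone lay below both control clones, and adjusted over the list alone 0 passed. FJX1 differed by −0.92 ± 0.18 (SE) and the tensin TNS3 by −0.47 ± 0.15. The list's median was −0.43, −0.36 and −0.20 in CDH26 clones 1, 2 and 3, and −0.17 and 0.17 in control clones 1 and 2. Without control clone 2 the median was −0.11 and the call was lost (adjusted p = 0.619).

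**Figure D2:**
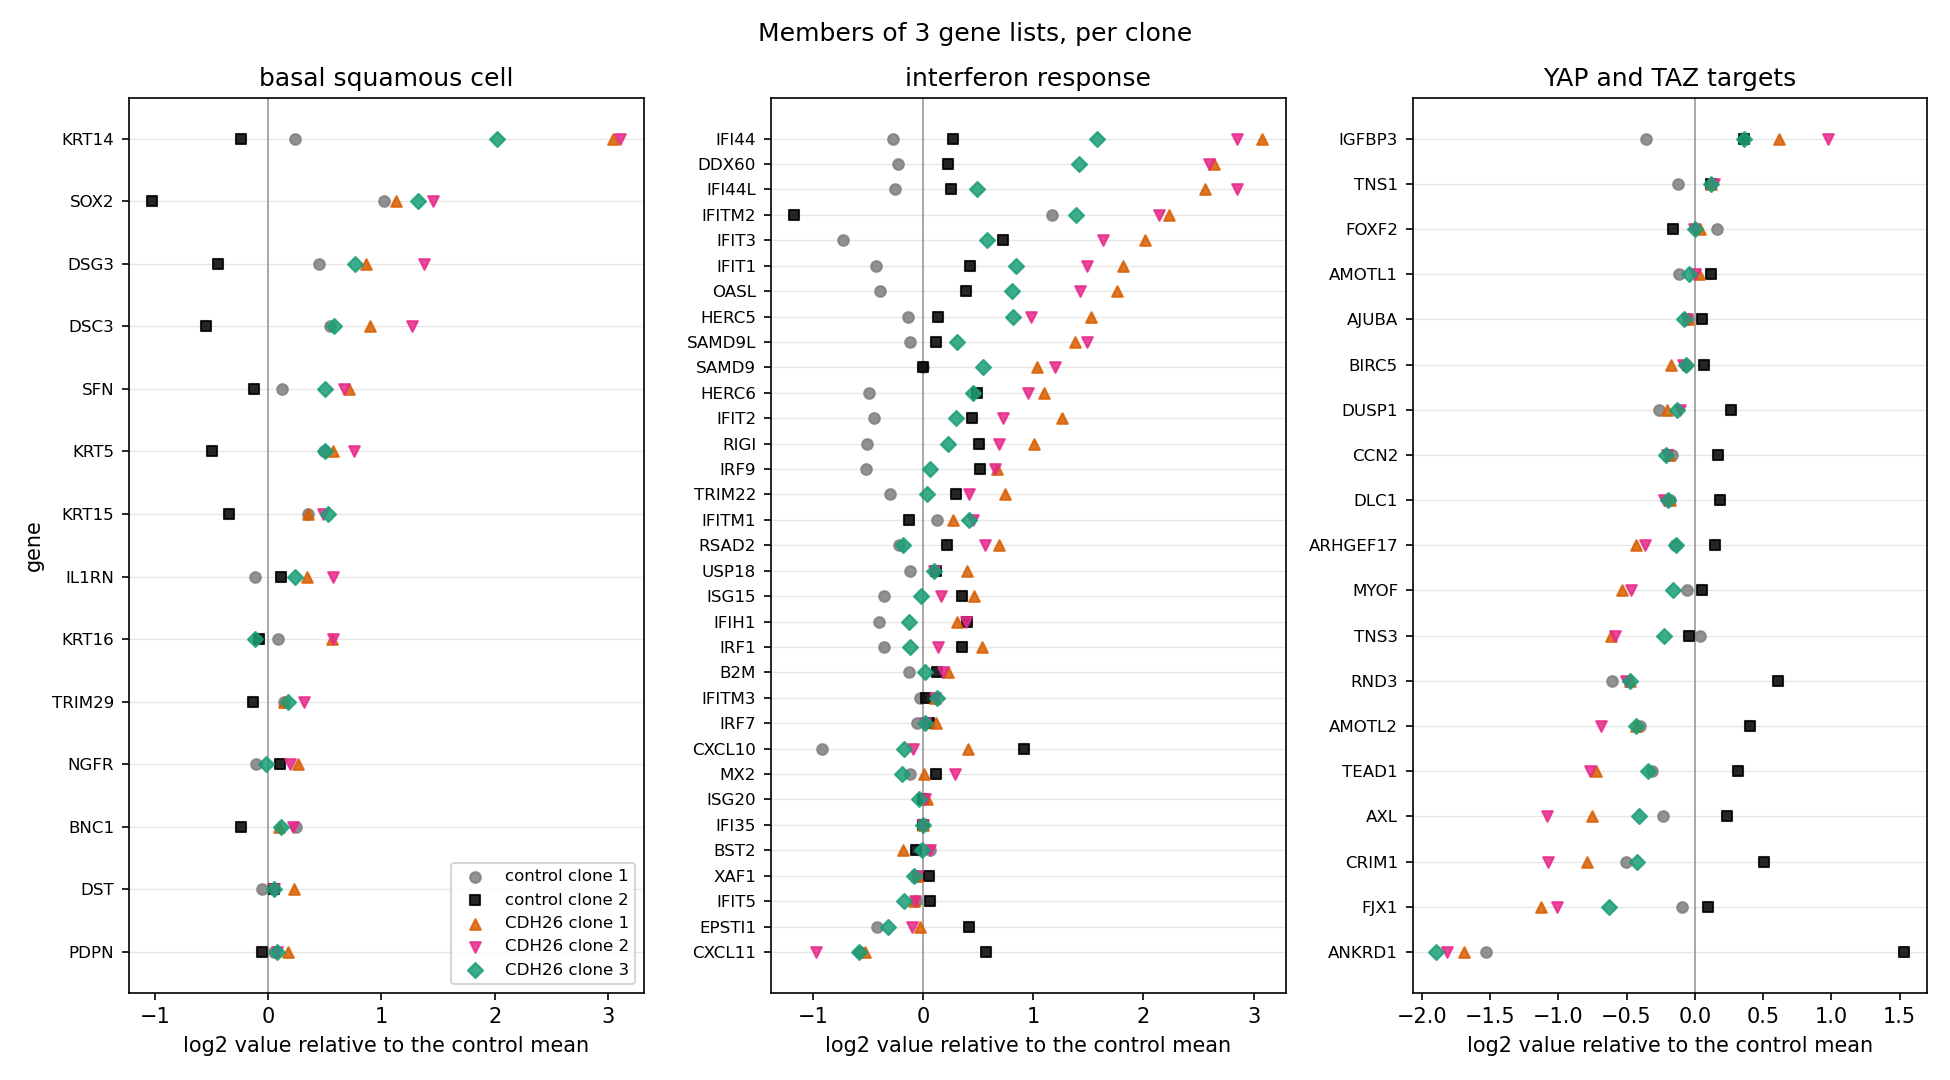
Log2 value per clone, relative to the mean of the control clones, for each measured member of the basal squamous cell, interferon response and YAP and TAZ target lists, ordered by the difference between groups; each symbol is 1 clone. KRT14 lies at 3.04, 3.11 and 2.02 in the CDH26 clones, and in many YAP and TAZ targets control clone 2 stands apart from the other arrays.

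Genes of hypoxia and glycolysis and of cholesterol synthesis were the remaining lists called. The 22 hypoxia and glycolysis genes had a median difference of 0.16 (camera, adjusted p = 0.00868; adjusted p = 0.58 with an estimated correlation); in 11 every CDH26 clone lay above both controls and in 3 below. NDRG1, a stress-induced gene of the hypoxia response, was higher by 1.11 ± 0.14 (SE) and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0309), while the glycogen-metabolism enzyme PGM1 differed by 0.45 ± 0.12. The call was lost without control clone 1 (adjusted p = 0.141) and without CDH26 clone 3 (adjusted p = 0.0714), and the median was 0.08 without control clone 2. The 20 cholesterol synthesis genes had a median of 0.10 and a camera adjusted p of 0.0493, with an adjusted p of 0.58 with an estimated correlation; INSIG1, a sterol-regulated brake on the pathway, differed by 0.84 ± 0.17 and the desaturase SCD by 0.51 ± 0.11, and adjusted over the list alone 0 passed. That call was lost without control clone 2 (adjusted p = 0.791, median 0.03; median 0.18 without control clone 1), without CDH26 clone 2 (adjusted p = 0.16) and without CDH26 clone 3 (adjusted p = 0.134).

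Cell adhesion lists, the group closest to the function of a cadherin, were not called over all genes. Of the listed symbols, older names of some genes included, 20 of 45 other cadherins and 14 of 31 adherens junction and catenin genes were measured. Coverage was fuller for the desmosome, 14 of 15, tight junction, 34 of 39, and other adhesion receptor lists, 29 of 35. Among the other cadherins, 20 members measured, FAT4 differed by 1.40 ± 0.21 (SE) and PCDH18 by 2.50 ± 0.61, while the list had a median of 0.04 and a camera adjusted p of 0.0756. In the desmosome list, 14 members, the desmocollin DSC2 differed by 0.95 ± 0.28 and the plakophilin PKP1 by 0.48 ± 0.15 (list adjusted p = 0.0866). Members of the adherens junction and catenin list included vinculin (VCL), at −0.60 ± 0.20, and PKP4, at 0.15 ± 0.04 (list adjusted p = 0.671). The tight junction list had an adjusted p of 0.175, with PARD6B at −0.45 ± 0.14 and CLDN17 at −0.14 ± 0.05, and the list of other adhesion receptors one of 0.169, with BCAM at −0.64 ± 0.32 and CD58 at 0.24 ± 0.10. The other cadherins were called without CDH26 clone 3 (adjusted p = 0.00332, median 0.08) and among genes with a different value on each array (adjusted p = 0.0322, median 0.41), and without control clone 1 the other adhesion receptors (adjusted p = 0.024). With an estimated correlation these calls were lost (adjusted p = 0.787, 0.647 and 0.385 in the same order). VCL was at −0.33 without control clone 2 and CLDN17 at −0.07 without control clone 1. Integrin genes had no named probe set in the annotation used here and were not analysed.

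Lists of signalling and growth were not called by camera with all clones weighted alike, while fry's mixed test called the cell cycle and stress response lists (adjusted p = 0.0224 and 0.0271). Of the listed symbols, 26 of 38 NF-kappa-B, 18 of 35 stress response and 44 of 52 cell cycle genes were measured. For Wnt targets it was 27 of 31 and for p53 targets 16 of 28. The NF-kappa-B and cytokine list, 26 members, had a camera adjusted p of 0.0841 and a median of −0.21; its members PTGS2 (cyclooxygenase 2) and NFKB1 differed by 1.18 ± 0.42 (SE) and −0.28 ± 0.08. Its median in the clones was −0.19, −0.22 and −0.20 with CDH26, and −0.26 and 0.26 in control clones 1 and 2. It was called with array weights (adjusted p = 0.0493; adjusted p = 0.639 with an estimated correlation), and its median difference was −0.34 without control clone 1 and −0.01 without control clone 2. The unfolded protein and integrated stress response list also had an adjusted p of 0.0841, with ASNS at −0.48 ± 0.13 and CRELD2 at −0.16 ± 0.04. In the cell cycle list, 44 members, the checkpoint kinase BUB1 differed by 0.46 ± 0.04 and was the 1 member past the threshold adjusted over the list alone, while CDC6 was at −0.21 ± 0.04 (list adjusted p = 0.132). Wnt targets had an adjusted p of 0.132, with the Wnt antagonist DKK1 at −0.66 ± 0.13 and CCND1 at −0.62 ± 0.25. The p53 targets had an adjusted p of 0.281, with CCNG1 at 0.25 ± 0.08 and TIGAR at −0.49 ± 0.21. Without control clone 1 the NF-kappa-B, stress response, cell cycle and p53 lists were called, with adjusted p of 8.34e-07, 0.0145, 0.00525 and 0.0453, and the cell cycle list also without CDH26 clone 1 (adjusted p = 0.0269). With an estimated correlation these were lost, with adjusted p of 0.385, 0.385, 0.619 and 0.385, and 0.765 for the cell cycle list without CDH26 clone 1. Without control clone 1 PTGS2 was at 0.70 and TIGAR at −0.77; without control clone 2 TIGAR was at −0.20, CCND1 at −0.38 and CCNG1 at 0.13.

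Lists for other cell types and states were included to see whether the clones differed in identity. Many were covered only in part. Of the listed symbols, 20 of 41 mesenchymal, 26 of 40 columnar, 20 of 30 type 2 cytokine and 16 of 32 collagen and matrix genes were measured. For leukocytes it was 18 of 36, for endothelium 15 of 21, for metallothioneins 11 of 12 and for ribosomal proteins 33 of 54. The mesenchymal list had a camera adjusted p of 0.145, with DKK1 at −0.66 ± 0.13 (SE) and the matrix cross-linking enzyme LOX at 1.61 ± 0.43; without control clone 1 it was called (adjusted p = 0.0361; adjusted p = 0.385 with an estimated correlation). The columnar and glandular list had an adjusted p of 0.493, with the epithelial transcription factor EHF at 1.18 ± 0.31 and VSIG1 at 0.72 ± 0.18. For the type 2 cytokine response of esophageal epithelium the adjusted p was 0.145, with CISH at 0.25 ± 0.13 and HPGD at 0.70 ± 0.38. Collagens and fibroblast matrix genes had an adjusted p of 0.46, with lumican (LUM) at 1.59 ± 0.42 and DPT at 0.07 ± 0.04, and leukocyte markers one of 0.504, with CD68 at 1.07 ± 0.33 and TPSAB1 at −0.17 ± 0.08. Endothelial markers (adjusted p = 0.723; ERG at 0.35 ± 0.13, SOX18 at −0.25 ± 0.13), metallothioneins (adjusted p = 0.69; MT1M at 0.09 ± 0.04, MT2A at −0.23 ± 0.11) and ribosomal proteins (adjusted p = 0.671; RPS28 at 0.20 ± 0.06, RPL14 at −0.09 ± 0.02) were not called. Without control clones 1 and 2 in turn CISH was at 0.12 and 0.38, ERG at 0.53 and 0.17 and SOX18 at −0.41 and −0.08. DPT was at 0.05 and RPS28 at 0.13 without control clone 1, and HPGD at 0.41 and TPSAB1 at −0.11 without CDH26 clone 2.

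**Figure D3:**
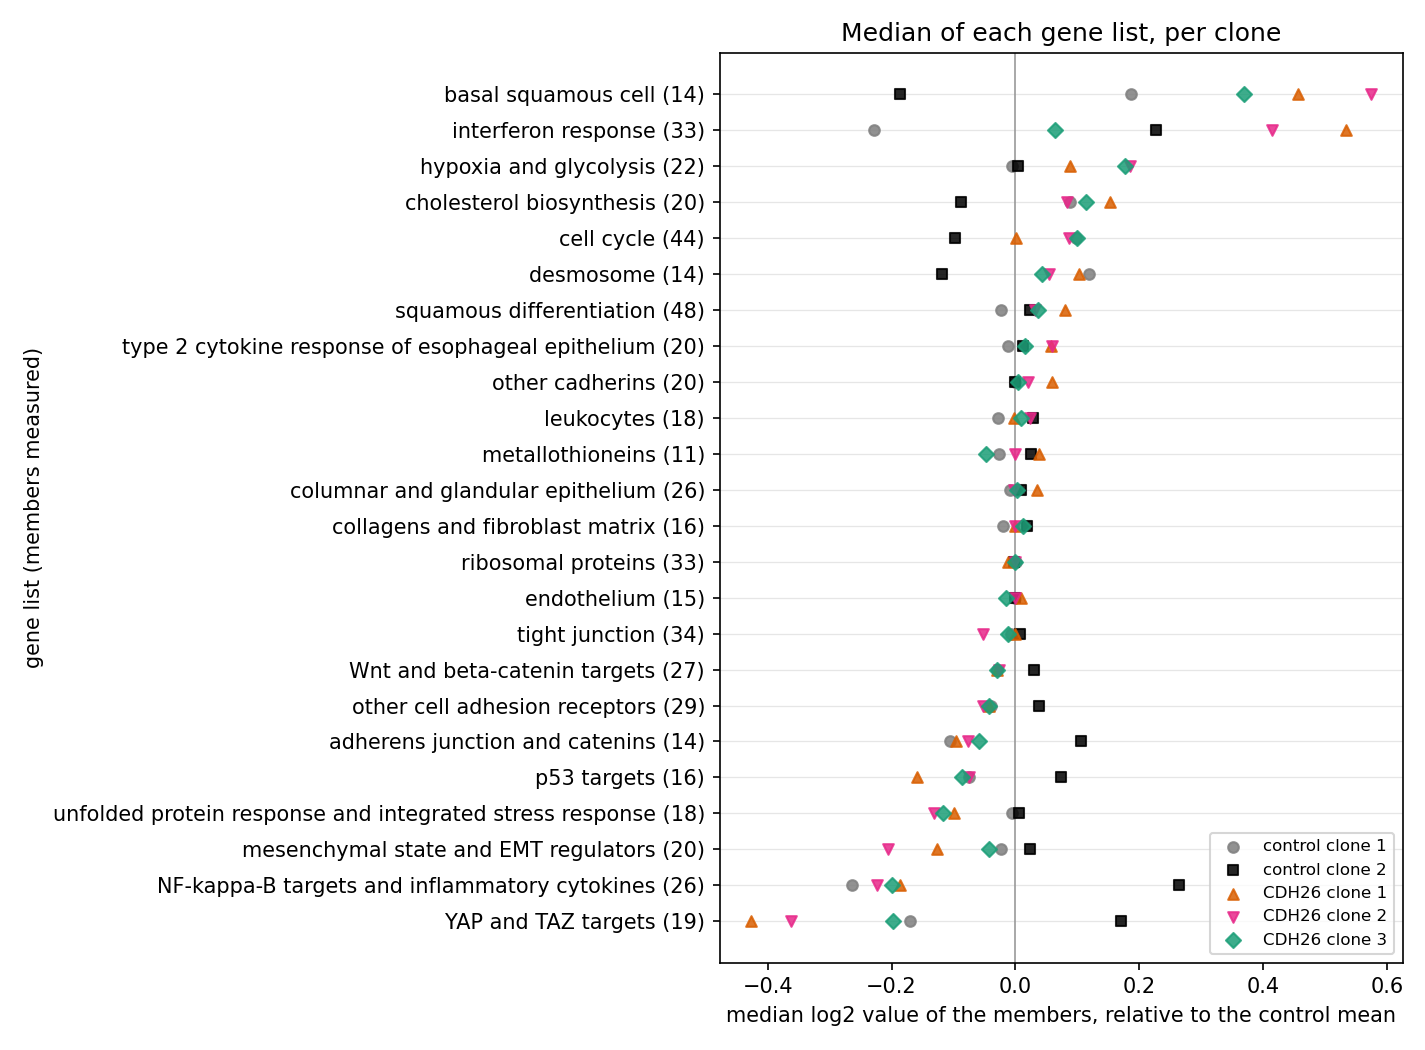
Median log2 value of the measured members of each gene list per clone, relative to the mean of the control clones, with the number of members in parentheses; each symbol is 1 clone. The basal squamous cell list lies at 0.46, 0.57 and 0.37 in the CDH26 clones against 0.19 and −0.19 in the control clones, and the NF-kappa-B list separates control clone 2, at 0.26, from the other 4 arrays.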

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

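In this part the split counts of the adjusted result and the correlation of adjacent genes were tests fixed beforehand; the splits of the 2-fold result, the wider gene spacing, the length trend and the spacing of 2-fold genes were chosen after the result was seen.

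Probe sets without a gene name lie outside the comparisons of named genes, and the largest differences in the table were among them. Probe set 16855723 was higher by 5.74 ± 1.81 (SE) log2 units in the CDH26 clones, at 7.35, 7.29 and 2.58 in clones 1, 2 and 3 against 0.07 and −0.07 in the control clones. Probe set 16855710 was higher by 4.98 ± 1.87 (SE), at 6.69, 6.47 and 1.77 against −0.49 and 0.49. The unadjusted p from limma was 0.0365 for 16855723 and 0.0592 for 16855710, so 16855710 is not among the probe sets counted next. Among the 28772 unnamed probe sets 36 met the criterion of a 2-fold difference and an unadjusted p under 0.05, 34 higher and 2 lower, and limma put 0 past the adjusted threshold.

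The differences between CDH26 and control clones were set against other arrangements of the arrays and against the order of genes on chromosomes. The 5 arrays split into 2 and 3 in 10 ways, too few for a share under 0.05: with limma the real split gave 0 genes past the adjusted threshold, the highest other split 0, and so all 10 as many, while the 2-fold criterion gave 48 genes in the real split and 87 in the highest other, CDH26 clones 1 and 2 against the remaining 3 arrays, so that 2 of 10 splits gave as many. Ranked differences of adjacent genes correlated at 0.158 across 14423 genes, which are not independent replicates, above 1000 shuffles of gene order (95% range −0.0168 to 0.0156), and still at 0.0891 for genes 11 to 20 places apart; a trend on gene length carried 0.00252 of the variance of the ranked differences (Spearman correlation with length −0.01), too little for such a correlation, which argues against length bias. Copy number differences between clones may contribute to the many small differences. The shuffles cannot tell them from any other cause that neighbouring genes share, so they do not single out copy number. The difference between the 2 control clones showed the same pattern, at 0.129. GC content was not tested, since no genome sequence was used here. Of 47 2-fold genes other than CDH26, 5 lay within 10 places of another, against a median of 2 in 1000 random sets (95% range 0 to 8), and 4, all but NEXN, lay so near one of the same direction, against a median of 2 (95% range 0 to 7), so copy number stays open for these, as does an effect of CDH26 itself, for which the clones give no separate test.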

How the results depend on the processing

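CDH26 stayed between 2.75 and 2.94 log2 units under all alternatives run for it, with adjusted p from 0.0106 to 0.77. It passed the threshold only among genes with a different value on each array (2.84), and was then the 1 gene called, against 0 in 14812. Fewer genes were tested there, and the prior variance was estimated without the tied genes. By the 2-fold criterion 68 genes qualified there, 57 higher and 11 lower, against 48, so the p-values depend on the tied genes too. With each clone left out in turn, 0 to 186 genes passed the adjusted threshold, the 186 without control clone 1, and the number of 2-fold genes ran from 15 to 160, of which 14 and 14 were among the 48. Every other alternative run gave 0 adjusted calls. The number of 2-fold genes was 86 over all probe sets, where more features are tested, and 112 if the values are natural logarithms, where every difference is larger. With the replicate block it was 106, 75 higher and 31 lower, of which 40 were among the 48; control and CDH26 clones share only a number, and the deviations of clones numbered alike correlated at −0.20 and −0.21. Replicate 3 exists only among CDH26 clones, so the block takes CDH26 clone 3 out of the estimates: they equal those without that clone, where the count was 114, to within 1.78e-15, and 100 of the genes are shared. The block changed 2 list calls, gaining other cadherins (adjusted p = 0.00336) and losing cholesterol synthesis (adjusted p = 0.0912). Camera with an estimated correlation called 0 lists and fry's directional test 0, against 6. Fry's mixed test called 3, of which hypoxia and glycolysis (adjusted p = 0.0375) was among the 6. Camera with an estimated correlation uses only the few residual degrees of freedom, which enters every loss. For hypoxia and glycolysis the estimate was −0.0086, so correlation between genes does not account for its loss. The other called lists had estimates from 0.07 to 0.49, above the preset 0.01, so correlation between genes also enters their losses. An estimated correlation also left 0 lists with array weights, the block, genes without ties and each clone left out. Leaving out 1 clone gave 4 to 9 called lists, and basal squamous cell was called each time. CDH26, the other named genes and the called lists kept their direction, though leaving out 1 clone moved 14 of 61 other named genes by over 1.5 times. The medians of 8 lists, called in no fit concerned, changed sign in 12 cases, to at most 0.03 in size, and without control clone 1 the 2-fold genes went from 43 higher and 5 lower to 71 higher and 89 lower. Array weights added the NF-kappa-B list (adjusted p = 0.0493), and genes with a different value on each array added other cadherins (adjusted p = 0.0322), for 7 called lists each. Centring on array medians moved nothing, since all medians were 0. Quantile normalization and the stricter brightness filter were not run, since centred values hold no level; the same keeps signal over background out of reach. Single probe sets, all probe sets, genes without ties, natural logarithms and the estimated correlation under other alternatives were chosen after seeing the data.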

Other observations

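Families related to the named genes were looked at after their values had been seen, and with all clones in the fit none of their members passed the adjusted threshold in limma. Among keratins, the simple-epithelial KRT7, KRT18 and KRT8 had log2 differences of −0.41 ± 0.18, −0.29 ± 0.20 and −0.22 ± 0.14 (SE), but KRT19, also of simple epithelia, was at 0.35 ± 0.11. KRT5, the basal partner of KRT14, was at 0.61 ± 0.34, KRT13 at 0.92 ± 0.55 and KRT10 at 1.06 ± 0.77. Much of this rests on control clone 2: without it KRT18 and KRT8 were at −0.04 and −0.03, KRT19 at 0.19, and KRT5, KRT13 and KRT10 at 0.11, 0.09 and 0.29; without control clone 1 the 6 were at −0.54, −0.41, 0.51, 1.10, 1.76 and 1.83 in this order, and KRT10 was at 0.57 without CDH26 clone 2. In the Schlafen family SLFN5 was at 1.01 ± 0.47 beside SLFN11 at 2.95 ± 0.51, while SLFN12, SLFN13, SLFN12L and SLFN14 were at −0.01, 0.07, −0.03 and 0.02. SLFN12, SLFN13, SLFN12L and SLFN14 each had the same value on several arrays, ties of unrecorded origin, so their small differences do not show that they were unchanged. The protocadherins PCDH7 and PCDH9 were at 1.48 ± 0.47 and 0.82 ± 0.26, and PCDH1 at −0.34 ± 0.22, but −0.01 without control clone 2 and −0.67 without control clone 1. Among ligands of the EGF receptor family, EREG and NRG4 were at 2.06 ± 0.45 and 1.22 ± 0.33 and HBEGF at −0.40 ± 0.29, but 0.00 without control clone 2 and −0.81 without control clone 1. Ephrin receptors went both ways, EPHA3 at 1.94 ± 0.51 and EPHA2 at −0.78 ± 0.19, and so did their ligands, with EFNA5 at 1.54 ± 0.80, EFNB1 at 0.51 ± 0.28, EFNA4 at 0.46 ± 0.07, EFNB2 at −0.59 ± 0.24 and EFNA2 at −0.56 ± 0.23. Without control clones 1 and 2 in turn EFNA5 was at 0.44 and 2.63 and EFNB1 at 0.91 and 0.11. The probe set of the microRNA gene MIR200C was at 0.59 ± 0.08, with 0.62, 0.68 and 0.46 in the CDH26 clones, and those of the other 4 genes of its family lay between −0.02 and 0.19. Each of these 4 also had ties between arrays.

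The tests of the next patterns, in CDH26 clone 3 and in control clone 2, were chosen after the results were seen.

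CDH26 clone 3 carried nearly as much CDH26 transcript as clones 1 and 2 and differed less from the controls in genes that were 2-fold higher or lower in both of those, though not in every list: the hypoxia and glycolysis median was 0.09, 0.19 and 0.18 in clones 1, 2 and 3. Of 89 genes at least 2-fold higher in clones 1 and 2, 86 were above the control mean in clone 3, at a median of 0.67 against 1.44 in the other clones. The median in the left-out clone over that in the other clones was 0.470 for clone 3 but 1.24 and 1.31 for clones 1 and 2. This argues against an effect of picking genes that would be alike for all clones. Clones 1 and 2 were closer to each other (correlation 0.78 across probe sets) than to clone 3 (0.53 and 0.65). Picking genes by deviations that clones 1 and 2 share is therefore not excluded. An admixture of control-like cells in the culture of clone 3 stays open, though the clones were grown from single cells. On the linear scale clone 3 showed 0.776 of the CDH26 departure. For the 89 higher genes the 5th to 95th percentile was 0.0529 to 0.630. CDH26 is 1 gene, however, carried by the construct, and its level per cell may differ between clones. The median share was 0.311 (quartiles 0.194 to 0.403) in the higher genes and 0.559 (quartiles 0.379 to 0.719) in the 37 lower ones. A single admixture share would make these medians equal, yet each median lay outside the quartile range of the other set. The quartiles give the spread between genes, not the precision of the medians. The medians were not compared by a test, and all shares come from 1 array of clone 3, so a single share is not excluded. A response that differs between clones, or differences between clones 1 and 2 and the rest that CDH26 did not bring about, may also underlie the smaller departures of clone 3. The design cannot part these.

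Control clone 2 stood apart from the other control and from the CDH26 clones, lying at least 0.5 log2 units above the rest in 236 genes and below in 232. Its NF-kappa-B list median of 0.26 compared with −0.26 in control clone 1 and −0.19 to −0.22 in the CDH26 clones. Array noise that is independent between genes would leave list members uncorrelated within groups. Yet 8 of 24 lists correlated above every one of 200 random lists of the same size, where 0.119 would by chance, while 12 lay within the 95% range. This correlation takes in the CDH26 clones too, so it does not single out control clone 2. Without control clone 1, where only CDH26 clones contribute, it was 0.51 for the interferon list but 0.01 for YAP and TAZ targets. Such noise is argued against between the control clones too, where 3 of 24 lists had a mean difference beyond every one of 1000 random flips of sign, against 0.0240 by chance. As control clone 2 minus control clone 1, the means were 0.64 for NF-kappa-B, 0.53 for YAP and TAZ targets and −0.18 for cholesterol synthesis. The YAP and TAZ and the cholesterol synthesis lists were also among those called between CDH26 and control clones. A difference in state or density between control cultures, or a clonal difference, may lie behind this. Both tests speak only to noise independent between genes and cannot exclude array effects shared by many genes. With 1 array per clone these were not separated.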
